A study of Mus musculus with 12 samples.

How the data were processed

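RNA was measured in 12 samples of sorted mouse spleen DC, 3 per group, in the groups wild-type CD8 DC, knockout CD8 DC, wild-type CD11b DC and knockout CD11b DC. The knockout carries CD11c-cre and floxed Xbp1 alleles, and the labels do not say whether the wild-type mice carry the Cre transgene. Per the labels' protocols, digested spleens were depleted of cells with CD3 or CD19, and live cells with MHC class II were sorted. CD8 DC were taken as CD24 high and CD8 positive with intermediate to high CD11c. CD11b DC were taken as CD24 low to intermediate and CD11b positive with high CD11c. RNA was extracted with a micro column kit, labelled with biotin and hybridised to Affymetrix Mouse Gene ST arrays, 1 array per sample, per the labels and the series' design text. The design text states 3 different mice of each genotype.

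The values are the authors' deposited log2 signals, made by robust multi-array average (RMA) per the submitters' processing notes, whose version and probe annotation are not given in the sources used here. RMA corrects the background, gives all arrays the same distribution of probe signals and summarises the probes of a feature. The log2 scale was read from the values, which run from 2.89 to 14.6 and are not centred by feature. The array medians were 7.45, 7.47 and 7.46 (wild-type CD8 DC), 7.48, 7.48 and 7.50 (knockout CD8 DC), 7.49, 7.51 and 7.51 (wild-type CD11b DC) and 7.57, 7.53 and 7.54 (knockout CD11b DC). No array values identical between samples were found. RMA compresses differences near the background, so folds of dim features are understated, and the scanner files were not used here, so signal over background is unknown. No scan date or slide was used, because the labels give none.

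The deposited values cover 35556 features. A platform annotation named 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 12146 were not listed. Features with several symbols or none were not named. For each symbol the feature with the highest mean over the 12 samples was kept, which left 19938 genes, and 999 genes had more than 1 feature. Of the genes 19856 matched the RefSeq genes of assembly GRCm38.p6 by gene number, and 0 symbols were updated. Those were used only for names and for which genes neighbour each other. The genome build behind the array features is not given in the sources used here, so no coordinates are printed.

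Each gene was fitted with limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8), with 1 mean per group over all 12 samples and empirical Bayes moderation. The fit had 8 residual degrees of freedom and a prior of 4.68. The contrasts were knockout minus wild type in CD8 DC and in CD11b DC, the difference of these effects, and CD8 minus CD11b DC in wild type. P-values are two-sided and adjusted by Benjamini-Hochberg over the 19938 genes within a contrast, and a gene passed at an adjusted p under 0.05. No dim features were removed. Values after ± are SE of the difference from the fit unless SD is written.

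Gene lists were written before the data were examined, 27 in all with 525 entries, of which 482 had a feature. Each was tested with camera (limma) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with an estimated correlation. Also counted were the members that passed over all genes and those that passed adjusted over the list alone. Lists share genes, such as Erp44 and Bloc1s1. In CD8 DC 21 lists passed with the preset and 5 with the estimated correlation, for the difference of the effects 14 and 2, and for the wild-type subsets 13 and 2. The median and the camera direction differed in sign for CD8 DC markers and cell cycle genes in CD8 DC, plasmacytoid DC markers in CD11b DC, neutrophil markers in the difference, and apoptosis regulators and B cell markers between the wild-type subsets. Another 5 lists were chosen after the data were seen.

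The genes named for each knockout contrast were fixed by a rule before the data were examined. The rule took Xbp1, the 5 RIDD substrates described in CD8 DC, the 8 largest rises and 8 largest falls among passing genes without overlap of the groups, and up to 4 passing members of each list with the smallest p. For the difference of effects it took the 6 largest of each sign. Between the wild-type subsets it took the 6 largest of each sign and up to 6 members of each DC marker list. Predicted genes and receptor segments were counted but not named by size. Hspa5, Hsp90b1 and genes in the closing section outside these sets were named after their values were seen.

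The replicate numbers were checked for pairing by the correlation, across genes, of deviations from the group means. Between CD8 DC and CD11b DC with the same number and genotype it was 0.343, 0.199 and 0.289 in wild type and 0.228, 0.417 and 0.301 in the knockout, each higher than with other numbers. These numbers therefore pair the samples of the subset comparison and of the difference of effects, in the way samples of one mouse or day would.

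The steps were tested on simulated data for all 19938 genes, drawn from the real means and spreads with 200 genes changed. For the knockout contrast in CD8 DC 48 of 67 genes changed by 0.5 log2 units were recovered, 67 of 67 changed by 1 and 66 of 66 changed by 2, with 15 unchanged genes called. For CD11b DC these numbers were 57 of 67, 65 of 67 and 66 of 66, with 10 unchanged genes called. For the difference of effects they were 49, 63 and 66, with 12 called, and for the wild-type subsets 54, 67 and 66, with 4 called. A list of 30 genes shifted by 0.5 was found by camera in each contrast, and 0 of the unshifted lists were called. The simulated genes were drawn independently and the lists at random. This run therefore could not show false calls of lists whose genes are correlated.

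Alternatives were the leaving out of each sample, the dimmest 40% of genes left out, every named feature or every feature tested, a shift of each array to the same median, repeated quantile normalization, empirical Bayes with trend and robust settings, array weights, minimum log2 differences of 0.58 and 1, a fit of the 6 samples of a comparison alone, the replicate number as a block, and the fry set test. The wild-type samples numbered 1 were also left out together, chosen after the data were seen.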

Results

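Conventional dendritic cells (DC) of the spleen, which take up antigen and present it to T cells, were compared between wild-type mice and mice whose Xbp1 gene is deleted by a Cre recombinase under the CD11c promoter. XBP1 is a transcription factor of the unfolded protein response. It becomes active when IRE1, an enzyme of the endoplasmic reticulum (ER) membrane, splices its mRNA, and IRE1 can also cut other mRNAs, a process called regulated IRE1-dependent decay (RIDD). CD8 DC (also called cDC1) and CD11b DC (cDC2) were sorted from C57BL/6 mice of about 8 weeks. RNA of 12 samples, 3 biological replicates in each of 4 groups, was measured on Affymetrix Mouse Gene ST arrays. The median log2 signal of an array lay between 7.451 and 7.567, and samples of one group correlated at 0.994 to 0.997 over all features. Samples of different subsets correlated at 0.970 to 0.979. The first principal component held 82.2% of the variance and separated the subsets, while the second held 4.57% and separated the genotypes. The wild-type samples numbered 1 stood apart from the other samples on the third component (2.84%), at 11.8 in CD8 DC and 11.6 in CD11b DC, against a highest value of 4.77 elsewhere. The number of arrays, 3 per group, limits the precision of every value below.

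The Xbp1 signal itself (feature 10374035) was measured first. In CD8 DC it was 11.42, 11.01 and 11.19 in the wild-type samples and 11.05, 10.96 and 11.02 in the knockout samples, on the log2 scale. In CD11b DC it was 10.97, 10.64 and 10.66 in wild type and 10.09, 10.02 and 10.38 in the knockout. The difference was -0.20 ± 0.12 (SE) in CD8 DC and -0.59 ± 0.12 in CD11b DC, and neither passed the limma test over all genes (adjusted p = 0.490 and 0.210). The labels do not say which part of the gene is deleted, and one feature summarises the whole transcript. A shortened mRNA can still give signal, so these values do not check the genotype labels.

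The comparison of knockout with wild-type CD8 DC asked which transcripts depend on Xbp1 in this subset. The largest rise was that of Asns, which encodes asparagine synthetase. Its log2 signal went from 9.05 ± 0.11 in wild type to 11.95 ± 0.20 in the knockout (SD, n = 3), a 7.46-fold difference (limma, adjusted p = 9.23e-09). Slc6a9, a glycine transporter gene, was 4.16-fold higher, and Phgdh, the first enzyme of serine synthesis, rose by 1.31 ± 0.09 log2 units. Among the genes that fell, Ccl22, which encodes a chemokine that attracts T cells, was 5.11-fold lower and Fcrla was 4.23-fold lower. Tapbp, which encodes the tapasin chaperone of MHC class I loading, was 3.00-fold lower, and Bloc1s1 fell by 1.68 log2 units.

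In all, 768 of 19938 genes changed in CD8 DC, of which 164 were higher and 604 lower in the knockout (limma, Benjamini-Hochberg adjusted). A change of at least 2-fold was seen in 60 of them, 13 higher and 47 lower. The 3 knockout and 3 wild-type values did not overlap in 764 of the 768 genes. Over all genes tested, 19.2% showed no overlap, where chance gives 10% on average. Genes of one array vary together, and every knockout array had a higher median over all features than every wild-type array of its subset. The excess over 10% alone is therefore no measure of a knockout effect. Other large rises were those of Cox6a2 (1.47 ± 0.13), Chac1 (1.30 ± 0.17), Slc1a4 (1.27 ± 0.11), Slc16a14 (1.25 ± 0.06) and Gpt2 (1.23 ± 0.10), in log2 units with SE. Further large falls were those of Cltrn (-2.02 ± 0.13), Fgl2 (-1.67 ± 0.11), Leprot (-1.61 ± 0.10) and Rnf130 (-1.58 ± 0.11). Leaving out 1 library moved the count to 501 without knockout replicate 3 and 504 without wild-type replicate 1.

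**Figure D1:**
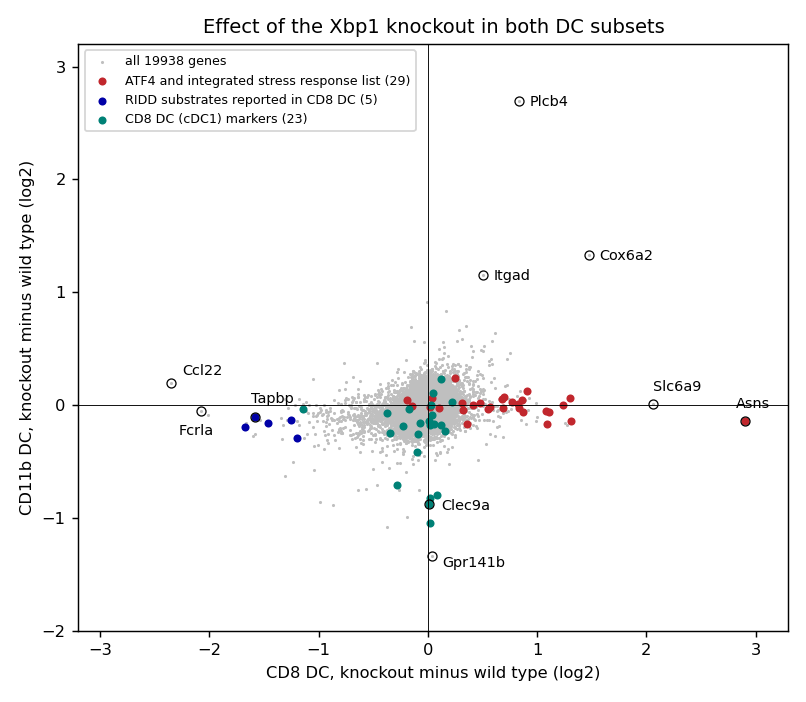
Each point is 1 of 19938 genes, placed by its knockout minus wild-type difference in log2 units in CD8 DC (horizontal axis) and in CD11b DC (vertical axis). Red, blue and green points are members of the 3 gene lists named in the key and open rings mark labelled genes; Plcb4 lies at 0.83 in CD8 DC and 2.70 in CD11b DC, and Tapbp at -1.59 and -0.11.

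Genes of the integrated stress response, a program driven by the transcription factor ATF4 when translation initiation is restrained, rose together in CD8 DC. Of 29 measured members 21 rose, none fell and 8 did not pass, with a median of 0.69 log2 units. The list test gave camera adjusted p = 9.43e-42, and adjusted p = 0.000534 with an estimated correlation. With adjustment over the list alone, 22 members rose. Beside Asns and Phgdh, the transfer RNA synthetase genes Cars (1.11 ± 0.07) and Sars (0.87 ± 0.05) and the mitochondrial serine hydroxymethyltransferase gene Shmt2 (1.09 ± 0.07) were among them. Atf4 itself rose by 0.59 ± 0.07. Among 9 sensors and transducers of the unfolded protein response Atf4 was the 1 gene that rose. Eif2ak3, which encodes the kinase PERK (-1.01 ± 0.09), Atf6b (-0.68 ± 0.05) and Dele1 (-0.60 ± 0.06) fell, and adjusted over the list alone the same numbers passed. That list shifted down (camera adjusted p = 0.00111), but not with an estimated correlation (adjusted p = 0.183).

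All 5 genes described as RIDD substrates in CD8 DC fell in the knockout. Their log2 differences were -1.68 ± 0.07 for Bloc1s1, -1.59 ± 0.06 for Tapbp, -1.46 ± 0.07 for Erp44, -1.26 ± 0.10 for Ergic3 and -1.19 ± 0.08 for Itgb2, the β2 integrin chain. The list test gave camera adjusted p = 1.49e-21, and adjusted p = 0.00533 with an estimated correlation. All 5 also passed adjusted over the list alone. This list may have been chosen on these same samples, so its direction is not independent evidence. Of 18 RIDD substrates described in other cells 5 fell and none rose (camera adjusted p = 0.000134, and adjusted p = 0.0216 with an estimated correlation). The 5 included Bloc1s1, Hgsnat (-1.14 ± 0.09), St3gal5 (-0.83 ± 0.08) and Galnt2 (-0.38 ± 0.05), and 5 fell when adjusted over the list alone. Bloc1s1 is on both RIDD lists, and the list from other cells was not tested without it. The median of those 18 genes was -0.03, with 13 of them below 0.

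**Figure D2:**
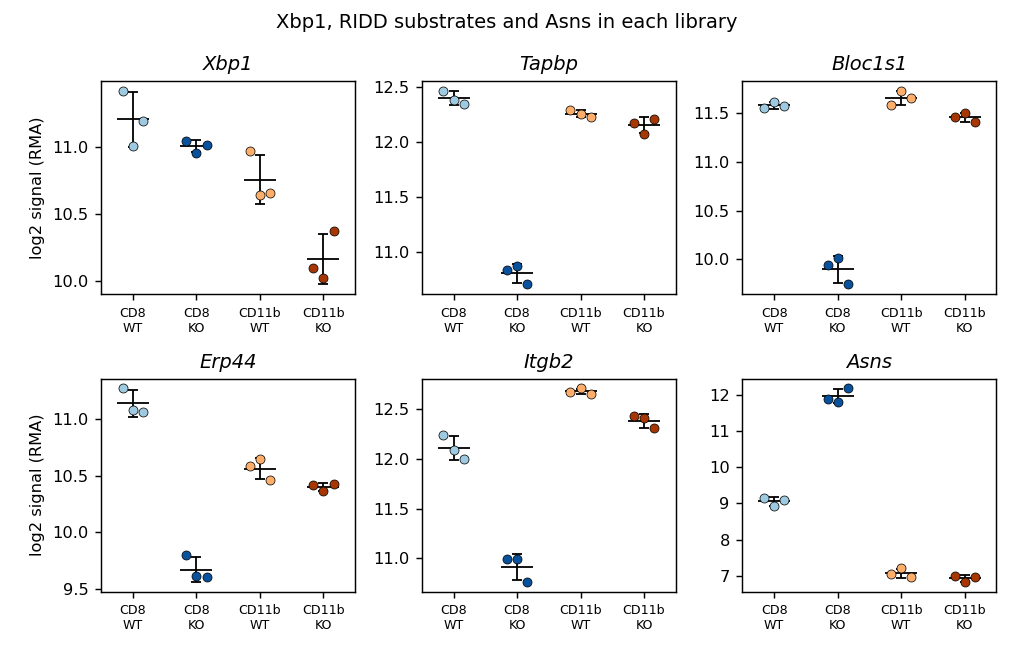
Log2 RMA signal of 6 genes in each of the 12 samples (points), with the group mean (bar) and SD (whiskers), n = 3 per group. Tapbp lies between 12.34 and 12.46 in wild-type CD8 DC and between 10.71 and 10.88 in knockout CD8 DC, and the axes do not start at 0.

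ER target genes of spliced XBP1 fell as a group in CD8 DC. Of 46 members 22 fell, none rose and 24 did not pass (camera adjusted p = 2.28e-22, and adjusted p = 0.0465 with an estimated correlation). Adjusted over the list alone, 30 fell and 3 rose. Erp44, Dnajc10 (-0.86 ± 0.07), Spcs3 (-0.80 ± 0.07) and the protein disulfide isomerase gene P4hb (-0.61 ± 0.05) had the smallest p among them. Erp44 is also on the CD8 DC RIDD list, which may have been chosen on these samples. The ER target list was not tested without it. ER chaperones and folding enzymes went both ways, with 8 of 20 lower and 2 higher, and 10 lower and 2 higher adjusted over the list alone. Txndc5 fell by 1.03 on the log2 scale. The 2 that rose, named after their values were seen, were the major ER chaperone genes Hspa5 (0.38 log2 units) and Hsp90b1 (0.30). The list shifted down (camera adjusted p = 8.93e-08), but not with an estimated correlation (adjusted p = 0.0778).

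Genes of N-glycosylation, which attaches sugar chains to proteins in the ER, included 9 of 28 that fell and none that rose. The number was 12 when adjusted over the list alone. Alg1 (-1.10 ± 0.07) and subunits of the oligosaccharyltransferase, Rpn1 (-1.09 ± 0.06), Stt3a (-0.57 ± 0.05) and Ddost (-0.48 ± 0.05), were among them. The list test gave camera adjusted p = 1.59e-11, and adjusted p = 0.0778 with an estimated correlation. Of 24 genes of lipid and sterol synthesis 12 fell, 14 when adjusted over the list alone, and none rose. Idi1 (-1.14 ± 0.16), Sqle (-0.89 ± 0.12) and Srebf2 (-0.98 ± 0.07), which encodes the main activator of sterol synthesis genes, lay on the sterol side of this list, and Dgat2 (-0.71 ± 0.08) makes triglycerides. Its list test gave camera adjusted p = 2.94e-14, and adjusted p = 0.0917 with an estimated correlation.

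Of 20 integrin and adhesion genes 5 fell, among them Itgb2, Itgal (-0.35 ± 0.05), Itgav (-0.48 ± 0.08) and Pecam1 (-0.43 ± 0.08). This list passed with the preset correlation (camera adjusted p = 4.20e-05) and with an estimated one (adjusted p = 0.0387), and 8 members fell and 1 rose adjusted over the list alone. Itgb2 is also on the CD8 DC RIDD list, and the integrin list was not tested without it. Tapbp was the 1 of 17 MHC class I genes that fell (3 adjusted over the list alone), and the list gave camera adjusted p = 0.0421 and adjusted p = 0.534 with an estimated correlation. Ifi30, a lysosomal thiol reductase (-0.31 ± 0.05), was the 1 of 11 MHC class II genes (2 adjusted over the list alone). That list gave camera adjusted p = 0.0139 and adjusted p = 0.216 with an estimated correlation. Of 21 DC maturation genes 5 fell, 7 adjusted over the list alone, including Ccl22, Ccl5 (-0.95 ± 0.10), Socs2 (-1.05 ± 0.17) and Tnfrsf4 (-0.64 ± 0.13). The maturation list passed with camera (adjusted p = 1.12e-05), but not with an estimated correlation (adjusted p = 0.252).

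Among 23 markers of the CD8 DC lineage Cd207 (-1.15 ± 0.14), which encodes langerin, and Naaa (-0.35 ± 0.06) fell, and 3 fell adjusted over the list alone. The list did not pass in one direction (camera adjusted p = 0.299), while the fry test of limma for changes in either direction did (adjusted p = 9.64e-07). Of 24 CD11b DC markers, 6 fell in knockout CD8 DC, including Cd4 (-1.01 ± 0.11), Esam (-0.60 ± 0.09), Rtn1 (-0.45 ± 0.06) and Zeb2 (-0.52 ± 0.10). Adjusted over the list alone 11 fell and 2 rose, and the list gave camera adjusted p = 1.84e-06 and adjusted p = 0.0602 with an estimated correlation. Among 12 B cell markers Fcrla, Cd22 (-0.61 ± 0.11) and Ighm (-0.52 ± 0.11) fell, 4 fell adjusted over the list alone, and the list gave camera adjusted p = 0.000727 and adjusted p = 0.217 with an estimated correlation. The immediate early genes Fos (0.70 ± 0.18), Fosb (0.61 ± 0.15) and Atf3 (0.69 ± 0.16) were 3 of 17 that rose, 7 adjusted over the list alone (camera adjusted p = 4.87e-07, and adjusted p = 0.252 with an estimated correlation). Ccr9 fell (-0.48 ± 0.12) and Cox6a2 rose among 11 plasmacytoid DC markers, the same numbers adjusted over the list alone (camera adjusted p = 0.686). Txndc5 was the 1 of 8 plasma cell markers that fell, 4 adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.135 with an estimated correlation).

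No member passed over all genes in the remaining 9 lists in CD8 DC. Interferon response genes (median 0.14, adjusted p = 0.649), cytosolic heat shock genes (0.15, adjusted p = 0.217), T cell markers (-0.16, adjusted p = 0.365), NK cell markers (-0.28, adjusted p = 0.365) and monocyte and macrophage markers (-0.19, adjusted p = 0.647) passed camera with the preset correlation only. The adjusted p-values just given are those with an estimated correlation. Cell cycle genes (0.03), apoptosis regulators (-0.02), neutrophil markers (-0.08) and erythroid markers (0.15) did not pass camera either way. Adjusted over their own list alone, 2 apoptosis regulators rose and 3 fell (fry test of limma for either direction, adjusted p = 0.00136), 3 NK cell markers fell and 1 erythroid marker fell. The calls of Fos, Fosb, Atf3, Ccr9, Ighm and Tnfrsf4 were each lost when at least 1 library was left out. Their highest adjusted p was 0.154, 0.142, 0.107, 0.160, 0.0744 and 0.0535, in that order. Cd22 (adjusted p = 0.0506) and Zeb2 (0.0528) did not pass when the 6 CD8 DC samples were fitted alone.

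The same question was asked in CD11b DC, where 7 of 19938 genes changed, 2 higher and 5 lower in the knockout (limma, Benjamini-Hochberg adjusted). Plcb4, which encodes a phospholipase C, had the largest rise, from 7.66 ± 0.16 to 10.36 ± 0.15 (SD, n = 3), a 6.48-fold difference (feature 10476443, adjusted p = 1.23e-08). Cox6a2, a cytochrome c oxidase subunit gene of muscle and plasmacytoid DC, was 2.52-fold higher. The genes that fell were Gpr141b (2.53-fold lower), Clec9a (1.84-fold), Gcsam (1.77-fold), Cd8a (-0.71 ± 0.09 log2 units) and Dlg2 (-0.48 ± 0.07). Clec9a, a receptor for dead cells, Gcsam and Cd8a are markers of CD8 DC. They were the 3 of 23 such markers that fell past the test over all genes, none rose, and 8 fell adjusted over the list alone. Xcr1 (-1.05 ± 0.17) and Rab7b (-0.80 ± 0.15) fell by more than Cd8a without passing. Of the 23 markers 19 lay below 0 and 4 above. The list shifted down (camera adjusted p = 2.72e-09, and adjusted p = 0.0323 with an estimated correlation), with a median of -0.18.

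**Figure D3:**
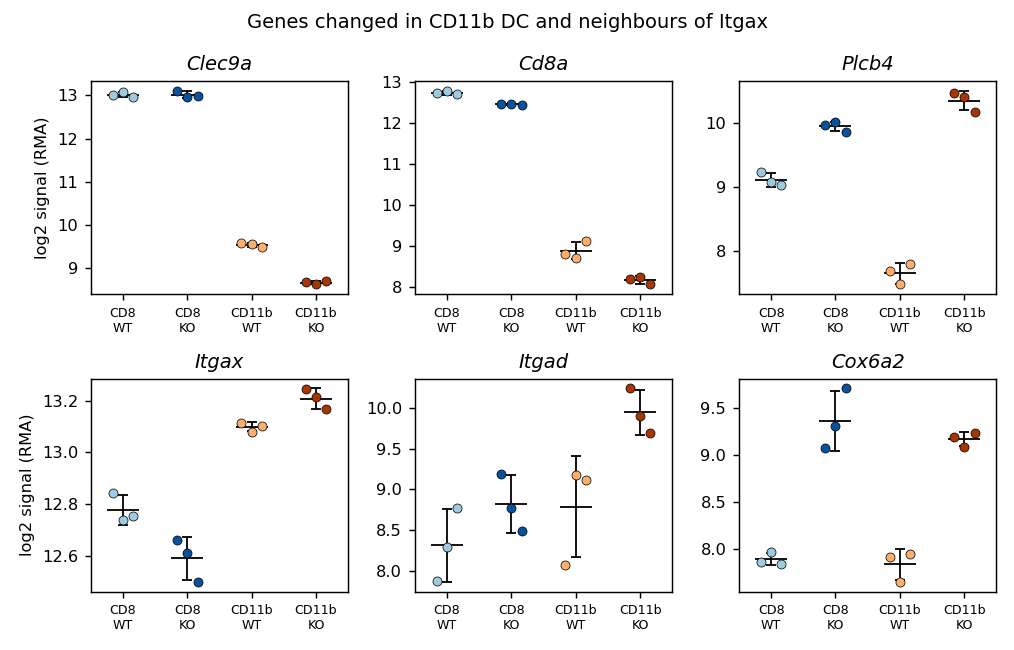
Log2 RMA signal of 6 genes in each of the 12 samples (points), with the group mean (bar) and SD (whiskers), n = 3 per group; the axes do not start at 0. Clec9a lies between 9.50 and 9.59 in wild-type CD11b DC and between 8.63 and 8.70 in the knockout, far below its level of 12.96 to 13.11 in CD8 DC.

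The CD8 DC RIDD substrates did not pass in CD11b DC, with log2 differences from -0.11 ± 0.06 for Tapbp to -0.30 ± 0.08 for Itgb2. Of the 5, 2 fell adjusted over the list alone, and the list gave camera adjusted p = 0.00203 and adjusted p = 0.270 with an estimated correlation. None of the 29 integrated stress response genes passed (median -0.01, camera adjusted p = 0.837). None of the 46 ER target genes of spliced XBP1 passed over all genes, while 10 fell adjusted over the list alone. Their median was -0.13, with camera adjusted p = 2.04e-11 and adjusted p = 0.270 with an estimated correlation. Genes of lysosomal proteins and of GPI anchor synthesis, lists chosen after the data were seen, also lay mostly below 0 in CD11b DC (24 of 27 and 21 of 24). A shift specific to the ER target genes is therefore not shown. NK cell markers had a median of -0.52 in the same comparison, with no member past the test over all genes and 4 of 11 lower adjusted over the list alone (camera adjusted p = 3.05e-06, and adjusted p = 0.270 with an estimated correlation). Of the 27 lists 10 passed camera with the preset correlation, and 1, the CD8 DC markers, with an estimated one.

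In CD11b DC 3 of the 7 genes, 2 higher and 1 lower, passed when the 6 CD11b DC samples were fitted alone, and Gpr141b, Gcsam, Cd8a and Dlg2 did not (adjusted p = 0.0997, 0.0819, 0.166 and 0.0997). Without wild-type replicate 1, which stood apart, 11 genes passed, and without both wild-type samples numbered 1, chosen after seeing the data, 12 passed. Dlg2 was also lost without some single libraries (highest adjusted p = 0.293). When each array was shifted to the same median, 13 genes passed, 2 higher and 11 lower (15.4% higher, against 28.6% in the values as deposited). At an unadjusted p under 0.05 there were 2220 genes, and 18.1% of all genes showed no overlap of the groups, where chance gives 10% on average. This share has the same limit as that in CD8 DC.

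Whether the knockout effect differed between the subsets was tested as the difference of both effects. It passed for 216 of 19938 genes (limma interaction, Benjamini-Hochberg adjusted), with 73 differences above 0 and 143 below. That fit left out the pairing of same-numbered samples. With the number as a fixed block 243 genes passed, 187 of them among the 216. Asns (3.04 ± 0.14 log2 units), Slc6a9 (2.05 ± 0.16), Phgdh (1.45 ± 0.12), Slc1a4 (1.45 ± 0.16) and Slc16a14 (1.41 ± 0.09) had more positive effects in CD8 DC. Gpr141b also had a positive difference (1.37 ± 0.20), from its fall in CD11b DC. Like the CD8 DC markers that fell there, it was far higher in wild-type CD8 DC than in wild-type CD11b DC. The most negative differences were those of Ccl22 (-2.55 ± 0.29), Fcrla (-2.02 ± 0.19), Cltrn (-1.93 ± 0.18), Plcb4 (-1.86 ± 0.13), Fgl2 (-1.51 ± 0.15) and the lysosomal membrane protein gene Lamp1 (-1.50 ± 0.16). That of Plcb4 came from its larger rise in CD11b DC.

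For the integrated stress response list the difference passed in 19 of 29 genes, all more positive in CD8 DC, with a median of 0.63 (camera adjusted p = 6.09e-39, and adjusted p = 0.000692 with an estimated correlation). For the CD8 DC RIDD substrates it passed in all 5, all more negative in CD8 DC, with a median of -1.30 (camera adjusted p = 1.37e-21, and adjusted p = 0.00516 with an estimated correlation). The RIDD list may have been chosen on these same samples, so it is not independent evidence of a difference between the subsets. ER target genes of spliced XBP1 differed in 7 of 46 genes (camera adjusted p = 6.29e-07), but the list did not pass with an estimated correlation (adjusted p = 0.282). Adjusted over the list alone the counts were 22, 5 and 16 in the direction named, and 1 ER target gene was more positive. The knockout effect on Cox6a2 was 1.47 in CD8 DC and 1.33 in CD11b DC, and its difference did not pass (adjusted p = 0.857).

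**Figure D4:**
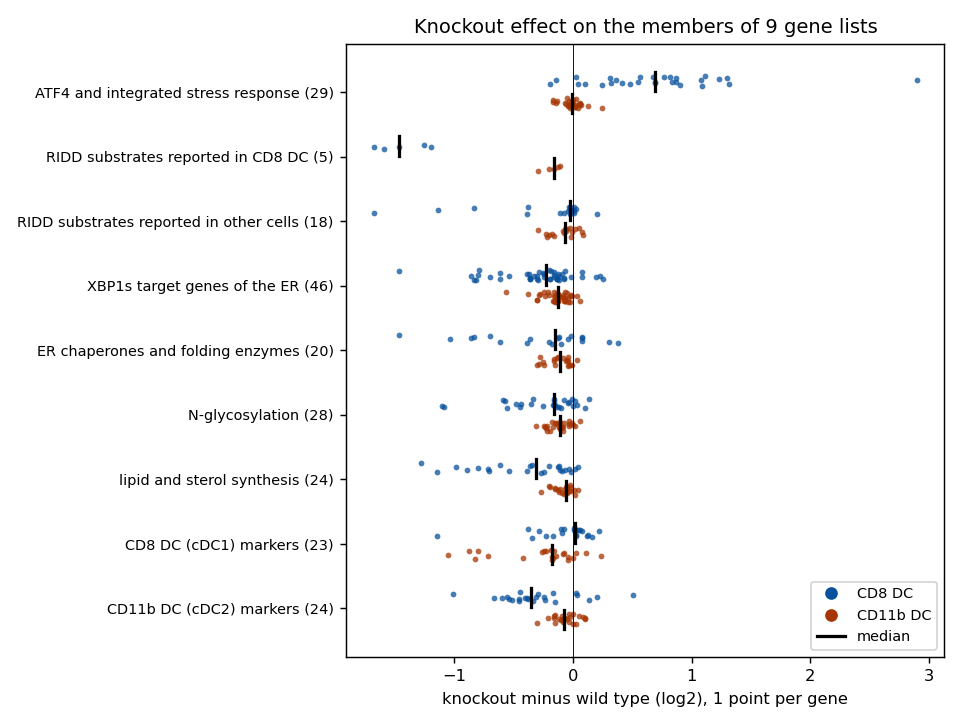
Knockout minus wild-type difference in log2 units for each member of the gene lists named on the vertical axis, with the number of members in brackets, in CD8 DC (blue) and CD11b DC (brown); black bars are medians and vertical scatter within a row has no meaning. The stress response list has a median of 0.69 in CD8 DC and -0.01 in CD11b DC, and the 5 RIDD substrates a median of -1.46 and -0.16.

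Wild-type CD8 DC and CD11b DC were compared to show how far the sorted subsets differ. All 23 markers of CD8 DC were higher in CD8 DC, with a median of 3.16 log2 units (camera adjusted p = 1.20e-28, and adjusted p = 0.000597 with an estimated correlation). Gcsam was 35.4-fold higher, and the chemokine receptor gene Xcr1 (4.32 ± 0.17 log2 units) and Clec9a (3.46 ± 0.06) were among them. Cd8a (3.86 ± 0.09), Cadm1 (3.41 ± 0.08), Cd24a (3.29 ± 0.08) and Naaa (2.31 ± 0.06), in log2 units, followed. Of 24 markers of CD11b DC 22 were lower in CD8 DC and 2 higher, with a median of -2.58 (camera adjusted p = 2.96e-20, and adjusted p = 0.00438 with an estimated correlation). Itgam, which encodes CD11b, was 12.3-fold lower, and Tlr7 (-3.78 ± 0.13), Dtx1 (-3.56 ± 0.09), Clec4a2 (-3.50 ± 0.11), Cd4 (-2.75 ± 0.11) and Zeb2 (-2.42 ± 0.10) were lower too. Clec4a4, an inhibitory lectin receptor gene, had the largest difference, at 48.9-fold lower. Adjusted over the list alone the same numbers passed in both lists.

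In all, 6361 genes differed between the wild-type subsets, 3377 higher and 2984 lower in CD8 DC (limma, Benjamini-Hochberg adjusted), and 961 differed by at least 2-fold, 384 higher and 577 lower. That fit also left out the pairing by number, and with a fixed block 6749 genes differed. The other large differences were those of Gpr33 (4.70 ± 0.36), Rab7b (4.69 ± 0.15), P3h2 (4.68 ± 0.17) and Gpr141b (4.61 ± 0.14) on the CD8 side. On the CD11b side they were those of Clec4a1 (-4.61 ± 0.28), Cyp4f37 (-4.48 ± 0.13), Dscam (-4.19 ± 0.18), Ptgs2 (-4.17 ± 0.17) and the interferon-induced gene Rtp4 (-4.07 ± 0.17). All 20 ER chaperones and folding enzymes were higher in CD8 DC, also adjusted over the list alone (camera adjusted p = 4.10e-12), and 36 of 46 ER target genes of spliced XBP1 were higher and 2 lower (camera adjusted p = 1.88e-12). With an estimated correlation these lists did not pass (adjusted p = 0.0616 and 0.235). Of 23 interferon response genes 16 were lower and 2 higher in CD8 DC, and of 17 immediate early genes 16 were lower. Both lists gave camera adjusted p = 2.07e-08, but did not pass with an estimated correlation (adjusted p = 0.597 and 0.471). Shifting each array to the same median gave 4318 higher and 2510 lower genes of 6828, or 63.2% higher against 53.1% in the deposited values.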

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

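The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the samples and the test of the difference of effects, which were planned. The genes and lists given first were picked because the knockout effect differed between CD8 DC and CD11b DC (limma interaction, adjusted p up to 0.0478 for the 48 genes named). No group had enough samples for a test of outlying samples.

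The difference of effects passed for 216 genes. It was positive, in log2 units of CD8 minus CD11b effect, for Asns (3.04), Slc6a9 (2.05), Phgdh (1.45), Slc1a4 (1.45), Slc16a14 (1.41), Gpr141b (1.37), Shmt2 (1.26), Chac1 (1.24), Gpt2 (1.24), Cars (1.17), Sars (0.93), Clec9a (0.89), Gcsam (0.84) and Atf4 (0.56). It was negative for the RIDD substrates Bloc1s1 (-1.48), Tapbp (-1.48), Erp44 (-1.30), Ergic3 (-1.13), Itgb2 (-0.90), Hgsnat (-0.85), St3gal5 (-0.67) and Galnt2 (-0.31). Among ER and glycosylation genes it was negative for Alg1 (-1.02), Rpn1 (-0.93), Txndc5 (-0.78), Dnajc10 (-0.73), Spcs3 (-0.59), Stt3a (-0.48), P4hb (-0.37) and Ddost (-0.35), and for the stress sensors Eif2ak3 (-0.88) and Atf6b (-0.60). Among sterol genes it was negative for Idi1 (-1.15), Srebf2 (-0.94) and Sqle (-0.77). Immune genes with a negative difference were Ccl22 (-2.55), Fcrla (-2.02), Fgl2 (-1.51), Socs2 (-1.28), Cd207 (-1.11), Ccl5 (-0.95), Cd4 (-0.93) and Ifi30 (-0.33). The others were Cltrn (-1.93), Plcb4 (-1.86), Lamp1 (-1.50), Leprot (-1.33) and Rnf130 (-1.33). Of the 48 differences 36 kept their call under every alternative run for single genes, which leaves out the minimum differences, and those of Galnt2, Ifi30 and Ddost were among the 12 that did not.

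By camera with the preset correlation the difference passed for 14 lists. Median differences were 0.63 for integrated stress response genes, 0.27 for immediate early genes and 0.16 for CD8 DC markers. They were -1.30 for RIDD substrates described in CD8 DC and -0.0511 for those in other cells, -0.10 for ER targets of spliced XBP1, -0.0802 for ER chaperones, -0.0684 for N-glycosylation, -0.19 for lipid and sterol synthesis and -0.0586 for MHC class II presentation. For integrins and adhesion the median was -0.15, for CD11b DC markers -0.26, for DC maturation -0.28 and for B cell markers -0.13. With an estimated correlation 2 of these lists passed, the integrated stress response and the CD8 DC RIDD substrates. The latter may have been chosen on these same samples and is not independent evidence.

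Over 100 regroupings of genotype within each subset, the real one included, 8 gave at least as many genes with a differing effect as the real 216, or 7 of the other 99, so chance cannot be excluded by this count. The highest other regrouping gave 721, and it is the true grouping with the genotypes of 1 subset mirrored, so it tests the sum of the knockout effects. All 8 kept or mirrored the true genotypes of CD8 DC, which leaves the large CD8 effect in place, and the highest of the 88 that parted those genotypes gave 9. Among the 10 splits that keep same-numbered samples together the real one gave 216 and the highest other 3. For the remaining counts 10 splits are too few for a share under 0.05, and in each 1 of 10 was as large as the real one. The real and highest other values were 768 and 10 in CD8 DC, 7 and 2 in CD11b DC, and 6361 and 0 between the wild-type subsets. For those subsets the other splits that part all 3 pairs of numbers gave at most 0, as did those that part fewer.

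The first pattern is the fall of CD8 DC markers in knockout CD11b DC. One explanation is that fewer CD8 DC were carried over into that sort, although its gate asked for low to intermediate CD24 and for CD11b. With the median of the shares lost that Clec9a (4.14%), Cd8a (2.69%) and Gcsam (1.23%) imply, the other 20 markers changed by 0.422 times the predicted amount (median, 95% bootstrap interval 0.217 to 0.600). These 3 genes prompted the pattern, so a ratio under 1 can follow from their choice and decides nothing. A single share matched Xcr1 (-1.05 ± 0.17, predicted -1.11) but not Cd36 (-0.26 ± 0.16, predicted -1.06) or Gcsam itself (-0.82 ± 0.08, predicted -4.35). Which misfits come from dim signal is unknown. Cd8a, whose share is the median, was also lower in knockout CD8 DC without passing (12.45, 12.45 and 12.44 against 12.72, 12.78 and 12.70). Part of the Cd8a fall in CD11b DC may be common to both subsets, which was not tested. Of the 100 genes most biased to CD8 DC 77 were lower in knockout CD11b DC, as carry-over would give. Their median was -0.13 (-0.18 to -0.09) against -0.01 over all genes. These 100 were ranked on the same samples and hold 4 genes that passed in that comparison, so they are no independent test. Both intervals resample genes, not mice, and leave out the spread between mice. Gpr141b, which also fell there, was likewise far higher in wild-type CD8 DC than in CD11b DC. Carry-over may be the cause, and a change within CD11b DC stays open too, untested.

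The second pattern is the rise of Cox6a2 and, without passing the test, of Itgad (0.50 ± 0.29 in CD8 DC, 1.16 ± 0.29 in CD11b DC) in the knockout. More plasmacytoid DC, which express Cox6a2, would raise their other markers. The median of the other 10 was -0.10 over both subsets (95% interval -0.26 to -0.00), which argues against more plasmacytoid DC. That interval resamples genes, not mice, and leaves out the spread between mice. Itgad and Cox6a2 are the next measured genes after Itgax, the CD11c gene, in assembly GRCm38.p6, and Itgad ranked 5 of 19938 by its mean rise, with Cox6a2 at 2, but this rank restates the rise that prompted the pattern and tests nothing. Without the wild-type samples numbered 1 the rise of Itgad was 0.28 in CD8 DC and 0.80 in CD11b DC (rank 16), and that of Cox6a2 1.46 and 1.37. With all 12 samples, the other 18 of the 10 nearest measured genes on each side had mean changes from -0.14 to 0.13, and Itgax itself -0.04. A mean over both subsets can hide opposite changes. Itgax lay at -0.19 ± 0.05 in CD8 DC and 0.11 ± 0.05 in CD11b DC, and neither passed. Extra copies of both genes on a Cre transgene built on the Itgax region may be a cause, which was not tested and which the labels do not settle, and an effect of Xbp1 loss stays open.

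The third pattern is the fall of Fcrla in knockout CD8 DC by 2.08 on the log2 scale. Fewer B cells carried over, in spite of the CD19 depletion, would lower the other B cell markers about as much. Their median change was -0.18 (95% interval -0.52 to -0.05, 11 markers), where the interval resamples genes, not mice. Cd79a lay at -0.38 ± 0.33 and Cd79b at -0.18 ± 0.17, and the lowest was Cd22 at -0.61. These values argue against fewer B cells as the cause for Fcrla. Whether the smaller falls of Cd22 and Ighm may come from B cells was not decided. An effect of Xbp1 loss within CD8 DC stays open as a hypothesis.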

How the results depend on the processing

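Leaving out the wild-type samples numbered 1 together, and each sample in turn for the lists, was chosen after seeing the data. No list that passed and no named gene turned its direction under any alternative run, but the balance of some counts did. The causes of the changes below were not tested, except that a minimum difference leaves fewer genes by construction. With a minimum log2 difference of 0.58 there were 242 genes in CD8 DC and 2012 between the wild-type subsets, 898 higher and 1114 lower in CD8 DC. With a minimum of 1 there were 60 in CD8 DC, 3 in CD11b DC (2 higher, 1 lower), 44 for the difference of effects and 961 between the subsets (384 higher, 577 lower), so the larger side changed from the 3377 higher and 2984 lower of the full count. In CD11b DC 13 genes passed after a shift to the same median, 11 with array weights, 3 with the 6 CD11b DC samples alone (2 higher, 1 lower) and 12 without both wild-type samples numbered 1; the 7 genes were among the 13, the 11 and the 12. Without both, 549 passed in CD8 DC, 167 for the difference and 5695 between the subsets. Leaving out 1 sample gave 501 (without knockout replicate 3) to 704 genes in CD8 DC, with 504 without wild-type replicate 1, and 6 to 11 in CD11b DC (11 without wild-type replicate 1).

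Lists that passed with an estimated correlation numbered 5 in CD8 DC, 1 in CD11b DC, 2 for the difference and 2 between the subsets. The fry test of one direction gave 3 in CD11b DC and 8 for the difference, and that of either direction 27 between the subsets. Over all alternatives except the minimum differences, applied to counts only, 53 of 61 named genes in CD8 DC stayed as called, passing or not. In CD11b DC 9 of 13 did, and between the subsets 23 of 23. For the difference 36 of 48 did (genes beyond the largest were followed there after seeing the data). Xbp1 in both subsets and the 5 RIDD substrates in CD11b DC never passed, so they had no call to lose. Of the 7 genes that passed in CD11b DC, Gpr141b, Gcsam, Cd8a and Dlg2 were lost under at least 1 alternative. The difference was lost under at least 1 alternative for Atf4, Cd207, Chac1, Ddost, Galnt2, Idi1, Ifi30, P4hb, Socs2, Sqle, St3gal5 and Txndc5. Lists that kept their call numbered 5 of 21 in CD8 DC, 1 of 10 in CD11b DC, 2 of 14 for the difference and 2 of 13 between the subsets. The scaling alternatives moved the median of all genes by at most 0.0463 log2 units.

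With the replicate number as a block in the paired comparisons, 243 genes (fixed block) or 308 (random block) passed for the difference and 6749 between the subsets, and no list call was lost. With the fixed block 187 of the 216 genes stayed, the differences of Ddost (adjusted p = 0.0715), Galnt2 (0.101) and Ifi30 (0.0763) were lost, and 16 lists passed, the 14 and 2 more. Wild-type and knockout samples share only a number, with correlations of 0.0839, -0.147 and -0.0233 in CD8 DC and 0.0937, -0.0987 and -0.187 in CD11b DC, so not every sample correlated best with its own number. There the block gave 542 genes in CD8 DC and 5 in CD11b DC. Signal over background, which limits dim genes on arrays, is not known here.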

Other observations

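The gene lists and tests in this part were chosen after the data were seen. Beyond the genes of the integrated stress response list, other cytosolic aminoacyl-tRNA synthetase genes, which load transfer RNAs with amino acids, rose in knockout CD8 DC. Of 12 that the earlier list did not hold, 6 rose and none fell, among them Yars (0.90 log2 units), Tars (0.88), Mars1 (0.85), Iars (0.82) and Lars (0.66). Of 19 amino acid transporter genes 8 rose, including Slc7a1 (0.83), Slc7a3 (0.74) and Slc38a2 (0.51), and 2 fell, Slc1a5 (-0.65) and Slc38a1 (-0.28). The 8 also hold Slc7a5 and Slc3a2 of the earlier list and Slc6a9 and Slc1a4, already named for their size, and the transporter list was not tested without them. These lists passed with an estimated correlation (camera adjusted p = 0.00743 and 0.0440). In CD11b DC no member of either passed. There the synthetase list shifted down (camera adjusted p = 0.0048), but not with an estimated correlation (adjusted p = 0.231), and the transporter list did not pass (camera adjusted p = 0.109).

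Genes of lysosomal proteins fell in knockout CD8 DC in 12 of 27 cases, with none higher. Among the genes that passed, the largest falls were those of Lamp1 (-1.58), the protease gene Tpp1 (-1.35), the cathepsin gene Ctsb (-0.61), Galns (-0.59) and Smpd1 (-0.59), while Lamp2 (0.02), Psap (-0.09) and Hexa (-0.05) did not pass. Of 24 genes of GPI anchor synthesis 4 fell, and that list did not pass (camera adjusted p = 0.116). In CD11b DC no lysosomal gene passed. The lysosomal list shifted down there too (camera adjusted p = 0.00856), but not with an estimated correlation (adjusted p = 0.342).

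A first hypothesis was that the rise of synthetase genes is larger for cytosolic than for mitochondrial enzymes. Mean changes in CD8 DC differed by 0.33 log2 units between 12 cytosolic and 16 mitochondrial synthetase genes (two-sided permutation test across genes, 100000 resamples, p = 0.00281). None of the 16 mitochondrial genes passed, but 13 of them lay above 0. Their list shifted up in CD8 DC (camera adjusted p = 0.0101), though not with an estimated correlation (adjusted p = 0.237). The permutation test compares sizes, so it cannot show a rise specific to the cytosolic enzymes. Genes are not independent replicates, so a larger rise of the cytosolic enzymes may be present but is not established. A second hypothesis was that lysosomal genes fall as a group. Camera with an estimated correlation gave adjusted p = 0.0164 over the 5 lists, so a joint fall may be present, found and tested on the same samples.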
